A study of Homo sapiens with 2 samples.

How the data were processed

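RNA was extracted with Trizol from the cells in growth phase and made into libraries of polyadenylated RNA with the NEBNext Ultra RNA kit, per the labels' protocols. There were 2 libraries, 1 from cells infected with the SLC26A4-AS1 virus and 1 from cells infected with the control virus. Reads were aligned with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3, per the submitters' processing notes. The strand setting of the counting is not given in the sources used here. The notes name the build hg19, but the identifiers and the start and end positions of all 22276 genes in the deposited tables equal those of GENCODE 29 on GRCh38, so coordinates are given on GRCh38.

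The deposited values are a signal per gene, not whole counts: in each table they are read counts that were rescaled to a library size common to both. Within a library, nearly equal steps separate the low values, and these steps gave the value of 1 read as 1.107 in the AS1 library and 0.903 in the control library. Divided by them, 100% of values lay within 0.02 of a whole number. The resulting reads, put through the quantile adjustment of edgeR with a dispersion of 0.05, returned the deposited values to a relative difference of at most 7.48e-09. The recovery was checked on simulated values with known reads. The design chosen before the data were examined assumed deposited counts, and the planned steps were applied to the recovered reads. Scaling as in the deposited values differed from TMM on the recovered reads by -1.0e-08 on the log2 scale, so both give the same ratios. Genes with fewer than 2 reads over both libraries do not appear in the tables.

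Library sizes were scaled with TMM (edgeR 4.0.16 in R 4.3.3), which gave factors of 0.885 for the AS1 library and 1.13 for the control library. CPM values are reads normalised to the scaled library size, each with an exact Poisson 95% interval. The log2 ratio is AS1 over control with 0.5 reads added to each. Its interval is the exact conditional binomial (Clopper-Pearson) 95% interval of the ratio, without added reads. With 1 library per group no p-value was computed. A gene was counted as higher or lower (the 2-fold rule) when it had at least 10 reads in total, at least 1 CPM in the higher library, an absolute log2 ratio of at least 1 and an interval that excluded a ratio of 1. The rule was tested on simulated counts for the comparison of these libraries. The changed genes in it were drawn from those with a mean level of at least 5 CPM, so recovery at lower levels was not tested. With counting error alone, 45 of 16337 unchanged genes passed (0.275%), and 100% of genes changed 3-fold or more were recovered. When an assumed scatter of 20% per gene was added, 482 of 16316 unchanged genes passed (2.95%) and 84% of genes changed 3-fold were recovered. With a scatter of 40%, 3479 of 16277 passed (21.4%), and 74% of genes changed 3-fold and 84% of those changed 4-fold were recovered. These simulated libraries had no trend with GC content, unlike the real ones. The rule without subtraction of the trend was not simulated on libraries that had it. The shares above therefore leave out genes that pass through such a trend. The scatter between cultures of these cells is not known, so the number of genes past the rule is a description of the libraries.

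Before the data were examined, 36 gene lists were fixed for DNA repair, cell cycle, stress, metabolism, signalling, thyroid identity and markers of other cell types. For each list the median log2 ratio of members with at least 10 reads was placed among 10000 random lists of the same size matched on mean level in 20 bins. After the trend with GC content had been seen, 10000 random lists were also drawn in which each member was replaced by a gene from the 200 nearest in GC content, gene length and level. GC content was taken from the longest GENCODE 29 transcript, which 22266 of the 22276 genes had, and gene length from the deposited tables. Either may differ from that of the transcript expressed in these cells. The trend itself was a regression of the log2 ratio on GC content (cubic) and log2 gene length (quadratic) over genes with at least 100 reads. Genes were named by a rule set before the data were examined. It took SLC26A4-AS1, SLC26A4, DDX5, TRIM25, MRE11, RAD50 and NBN, the 12 protein-coding genes of at least 5 CPM ranked highest and the 12 ranked lowest by the interval bound nearest to a ratio of 1, up to 4 members per list by the same bound, and the genes within 1 Mb of SLC26A4-AS1. Where 5 or fewer members of a list passed in a direction, all are named, except for a few genes and 1 list that are not reported here, and those beyond the rule were chosen after their values were seen. So were MT-RNR2, GCLC, GCLM, TXNRD1, HMOX1, RAD51B and, among the closing observations, the intestinal and aryl hydrocarbon receptor genes and individual levels of KRT8, KRT18, EPCAM, VIM, LYZ, HSP90AB1, CLSPN and EIF3F.

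Alternatives planned beforehand were scaling by total counts, by DESeq2 1.42.0 size factors or by the upper quartile, leaving out mitochondrially encoded genes, 2 reads added, other fold, level and interval limits, members with at least 100 reads, and the mean in place of the median. The subtraction of the GC and length trend, the GC-matched lists and the scaling as deposited were added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.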

Results

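Polyadenylated RNA was sequenced from cells that the labels name C643, an established line derived from an anaplastic thyroid carcinoma, after stable infection with a lentivirus that overexpresses the long noncoding RNA SLC26A4-AS1 or with a control virus (PLVX). Each group was 1 library, and the series' design text states that no replicates were made. The library from cells with the SLC26A4-AS1 virus (the AS1 library) held 18148391 reads assigned to genes, and the library from cells with the control virus (the control library) held 17424256. The deposited tables listed 22276 genes, of which 20188 had a read in the AS1 library and 21734 in the control library. The identity of the cells rests on the labels: the epithelial keratin gene KRT8 was at 8566 and 6338 CPM, while the mesenchymal gene VIM had 10 and 17 reads, which is unusual for a line of this origin. Levels are given as TMM-scaled CPM, the read count normalised for library depth, and log2 ratios are AS1 over control. Intervals are 95% counting intervals. They cover neither the spread between cultures nor PCR copies, so every difference below is one between these libraries and has no replicate check.

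SLC26A4-AS1 itself separated the libraries. The transcript (chromosome 7, 107653968 to 107662151 on GRCh38, minus strand, annotated as an antisense gene) had 13690 reads in the AS1 library, or 853 CPM (838 to 867), and ranked 155 among all genes there. It had 0 reads in the control library, where the exact Poisson interval reached 0.187 CPM. A set limit of 3 reads corresponds to 0.152 CPM there. Against this limit of 3 reads, the level of SLC26A4-AS1 was 5597-fold higher in the AS1 library. The exact interval of the ratio allowed a value as low as 4551-fold. SLC26A4, the overlapping gene on the plus strand that encodes the iodide and chloride exchanger pendrin, had 0 reads in the AS1 library and 2 in the control library, so a difference in its level was not detectable at this depth. Within 1 Mb of SLC26A4-AS1 the tables listed 19 other genes, SLC26A4 among them, and 13 had at least 10 reads. Of these 13, AC002467.1 passed the 2-fold rule as higher (log2 ratio 1.21, interval 0.22 to 2.33), at 25 against 13 reads. The 5 that passed as lower were DLD (-1.69), DUS4L (-1.20), PNPLA8 (-1.85), THAP5 (-1.87) and DNAJB9 (-1.08). The laminin gene LAMB1 (0.64), COG5 (-0.39), CBLL1 (-0.40) and HBP1 (-0.07) were among the other 7, which did not pass.

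**Figure D1:**
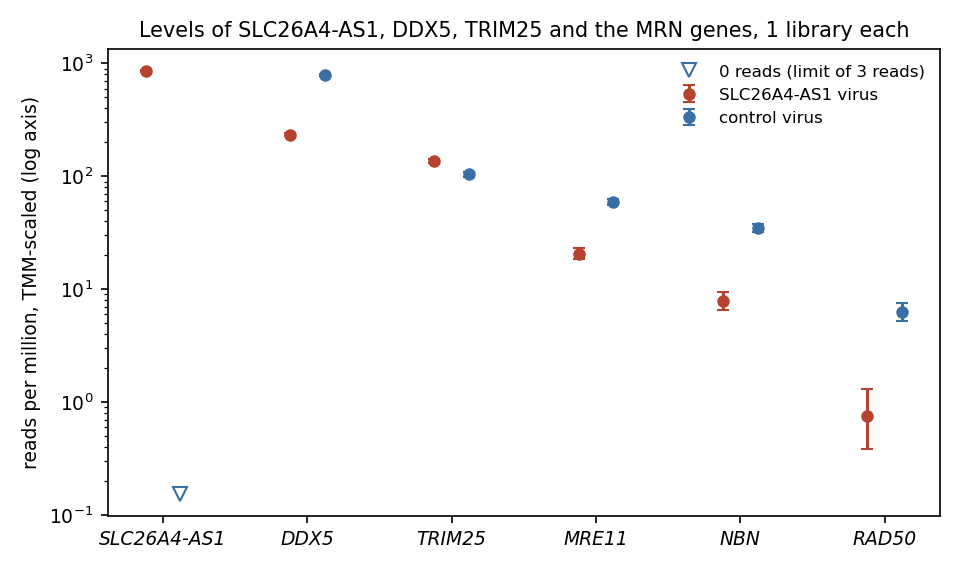
TMM-scaled CPM (log axis) for SLC26A4-AS1, DDX5, TRIM25, MRE11, NBN and RAD50 in the AS1 library (red) and the control library (blue), 1 library each, with exact Poisson 95% intervals on the filled points. The open triangle marks 0.152 CPM, the level of 3 reads, for the 0 reads of SLC26A4-AS1 in the control library. DDX5 and the 3 MRN genes lay lower in the AS1 library, and TRIM25 lay slightly higher.

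Across the transcriptome, 1878 genes were at least 2-fold higher and 3014 at least 2-fold lower in the AS1 library, out of 16547 genes with at least 10 reads in total. Protein-coding genes of at least 5 CPM were ranked by the interval bound nearest to a ratio of 1, and the highest was CYP1A1, a cytochrome P450 induced by the aryl hydrocarbon receptor, at 39.3 against 3.55 CPM (log2 ratio 3.46, interval 3.11 to 3.84). Other metabolic enzymes among the 12 highest-ranked genes were the aldehyde dehydrogenase ALDH3A1 (2.77), the aldo-keto reductase AKR1C1 (2.56), the argininosuccinate synthase ASS1 (2.35), the mitochondrial gluconeogenic enzyme PCK2 (2.30) and the extracellular superoxide dismutase SOD3 (2.57). The rest were the replication licensing factor CDT1 (2.27), the microtubule-binding tau gene MAPT (2.93), the corepressor TLE2 (2.68), the circadian transcription factor DBP (2.46), ZNF581 (2.56) and EMID1 (2.93). At the other end, MYH15 had 5 reads against 223 (-5.05, interval -6.82 to -3.94), and CFAP44, an axonemal protein gene, had 14 against 276 (-3.96). BIRC3, an inhibitor of apoptosis, was at 1.99 against 24.3 CPM (-3.59). The kinetochore motor CENPE (-3.37), the recombination genes BRCA2 (-3.28) and GEN1 (-3.22) and the splicing-associated genes LUC7L3 (-2.92) and PRPF39 (-3.15) were also among the 12 lowest-ranked genes. The others were ZNF780A (-3.48), RAPGEF6 (-3.55), FAM111B (-3.17) and FPGT (-3.53). The balance of the calls moved with the scaling: with plain total counts, which shift every log2 ratio by -0.35, there were 777 higher and 4257 lower genes, and with upper-quartile scaling there were 2452 higher and 2641 lower.

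The direction of a gene followed the base composition of its transcript. Among 11734 genes with at least 100 reads, the log2 ratio rose with the GC content of the longest transcript (Spearman's rho across genes 0.743; genes are not independent replicates). In the 10% of these genes with the lowest GC content (30.2% to 38.6%) the median log2 ratio was -1.42, and 70.3% were at least 2-fold lower. In the 10% with the highest GC content the median was 0.90, and 40.5% were at least 2-fold higher. The median GC content was 58.5% in the higher genes, 40.3% in the lower genes and 50.3% in the genes that passed in neither direction. The lower genes also had a larger deposited gene length, with a median of 6167 bases against 3266 in the higher genes. The log2 ratio also rose with mean level (Spearman's rho 0.253). GC content and gene length together accounted for 55.7% of the variance of the log2 ratio. After this trend was subtracted, 976 genes were at least 2-fold higher and 1387 at least 2-fold lower. The 5 lower genes near SLC26A4-AS1 then lay between -0.66 (DLD) and -0.33 (DNAJB9), and CYP1A1 (2.98) and MYH15 (-4.61) kept large differences. Each gene group below with at least 3 measured members is therefore given with the percentile of its median among 10000 random lists matched on expression level and among 10000 lists matched on GC content, gene length and level.

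**Figure D2:**
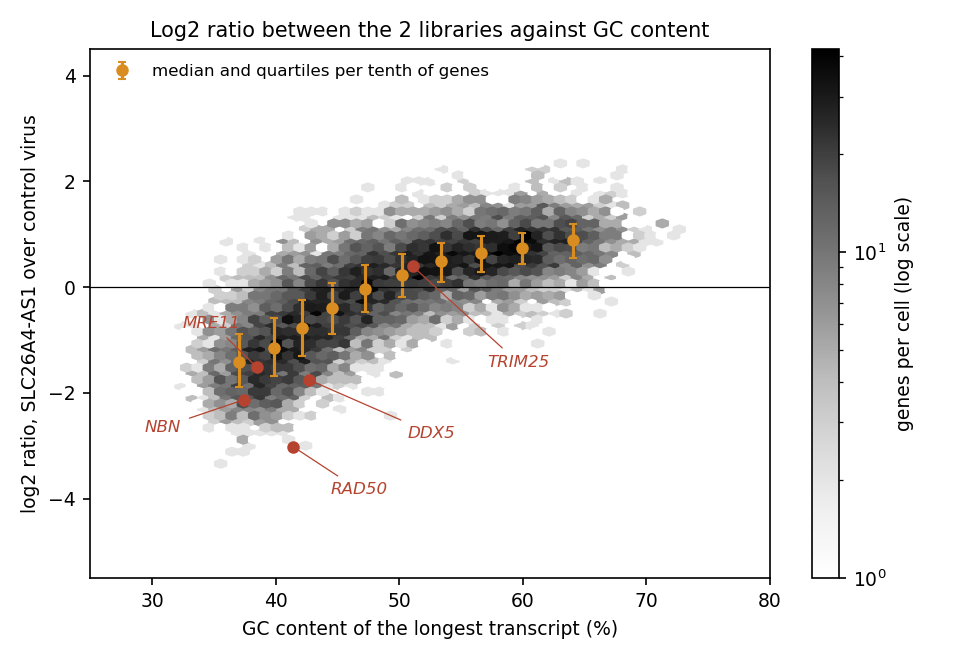
Log2 ratio of each gene with at least 100 reads (AS1 over control library, vertical axis) against the GC content of its longest transcript in percent (horizontal axis). Grey cells show the number of genes on a log scale, orange points the median and quartiles of 10 groups of equal size by GC content, and red points MRE11, NBN, RAD50, DDX5 and TRIM25. The medians run from -1.42 to 0.90. MRE11 and NBN lie at low GC content, and RAD50 lies lowest of these 5 genes.

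The study is known to concern DDX5, TRIM25 and the MRE11-RAD50-NBN (MRN) complex, which senses DNA double-strand breaks. All 3 MRN genes were lower in the AS1 library. MRE11 (chromosome 11, 94415578 to 94493908) was at 20.7 against 59.5 CPM, a log2 ratio of -1.52 (interval -1.70 to -1.34). NBN (chromosome 8, 89933336 to 90003228) was at 7.91 against 34.8 CPM (-2.13, interval -2.42 to -1.86). RAD50 (chromosome 5, 132556019 to 132646344) had 12 against 124 reads (-3.02, interval -4.07 to -2.22). The RNA helicase DDX5 (chromosome 17, 64499616 to 64508199) was at 233 against 786 CPM, a log2 ratio of -1.75 (interval -1.80 to -1.70). The ubiquitin ligase TRIM25 (chromosome 17, 56836387 to 56914080) was at 137 against 104 CPM, which did not reach 2-fold (0.39, interval 0.30 to 0.48), and with total counts its log2 ratio was 0.038. The median of the MRN list lay at percentile 0.30 of the level-matched lists and at percentile 3.69 of the GC-matched lists. After the GC and length trend was subtracted, MRE11 (-0.29) and NBN (-0.83) no longer passed the 2-fold rule, while RAD50 (-2.08) and DDX5 (-1.03) did. Against the 200 genes nearest in GC content, length and level, the percentiles were 47 for MRE11, 13 for NBN, 2.5 for RAD50, 6.5 for DDX5 and 59.5 for TRIM25. Each of these 5 genes overlaps another annotated gene, and the strand setting of the counting is not given in the sources used here. Among 12 measured genes listed as DDX5 and its partners, the microprocessor gene DGCR8 (-1.12) was lower besides DDX5, and 0 were higher (percentiles 12.6 and 12.5).

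Homologous recombination genes were lower as a group. Of 23 measured members, 14 were at least 2-fold lower and 0 were higher, with a median log2 ratio of -1.65. They included the tumour suppressor BRCA2 at 3.18 against 31.1 CPM, the Holliday junction resolvase GEN1 (-3.22), the helicase BRIP1 (-2.84) and BARD1 (-2.47), the partner of BRCA1. The median lay below all random lists of both kinds (percentile 0.00 and 0.00). After the trend was subtracted, 6 of the 23 were lower and 1 was higher, RAD51B (0.76 before and 1.40 after), with a median of -0.83. End-joining genes went both ways: 6 of 14 were lower, among them RIF1 (-2.79), SHLD2 (-2.10) and the DNA-dependent kinase PRKDC (-1.29), and 3 were higher, the polymerases POLL (1.63) and POLM (1.30) and MAD2L2 (1.35). Their median of -0.74 lay at percentile 1.24 of level-matched and 3.09 of GC-matched lists, and after the trend RIF1 was lower and POLL higher. In the damage checkpoint list 8 of 22 genes were lower, led by CLSPN (-3.16), TOPBP1 (-2.43) and the kinases ATR (-2.37) and ATM (-2.09), and 1 was higher. Its median of -0.28 was inside the central 95% of both kinds of random list (percentiles 10.1 and 46.7), but its mean of -0.73 lay at percentile 0.06 of level-matched lists. After the trend 4 were lower and 1 was higher. Of 14 Fanconi anemia genes, 3 were lower (FANCI at 43.3 against 161 CPM, FANCM, -2.21, and FANCB, -2.23) and 2 higher (FANCE, 1.75, and FANCG, 1.02), with a median of -0.08 (percentiles 43.0 and 39.8). Of 22 mismatch and excision repair genes, 3 were lower, among them XPA (-1.42) and ERCC5 (-1.78), and 4 higher, NTHL1 (1.41), ERCC1 (1.16), ERCC2 (1.11) and APEX1 (1.06), with a median of 0.22 (percentiles 61.2 and 66.2). After the trend, 0 Fanconi anemia genes were higher and 1 lower, and 1 mismatch and excision repair gene was higher and 2 lower. Within the homologous recombination and end-joining lists the log2 ratio rose with GC content (Spearman's rho 0.85 and 0.81). In the damage checkpoint, Fanconi anemia and mismatch and excision repair lists rho was 0.72, 0.74 and 0.78.

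Cell division genes were also lower on balance. Of 35 mitotic genes, 18 were at least 2-fold lower and 0 higher, with a median log2 ratio of -1.03 (percentiles 0.00 and 0.00). The largest differences were in CENPE, the centromere protein CENPF (-2.69), the spindle protein ASPM (-2.64) and the motor KIF11 (-2.39). Within this list the log2 ratio rose with GC content (Spearman's rho 0.89 over the 35 genes). After the trend was subtracted, 8 of the 35 were lower. Of 37 replication and E2F target genes, 9 were lower and 2 higher, with a median of -0.45 (percentiles 0.30 and 0.00), and 8 were lower and 1 higher after the trend. The polymerase subunit POLE2 (-2.25), RFC3 (-1.76) and POLA1 (-1.75) were lower, whereas CDT1 at 320 against 66.2 CPM and the polymerase subunit POLD1 (1.05) were higher. Of 14 measured replication-dependent histone genes, whose main transcripts lack a poly(A) tail, HIST2H2BE (1.13) was higher and HIST4H4 (-1.11) lower, with a median of -0.13 (percentiles 62.9 and 36.7).

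Ribosomal protein genes lay on the other side, and nuclear genes of respiration did so by their median. Of 44 ribosomal protein genes, 33 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.25, above all random lists of both kinds (percentile 100 and 100). RPL18 was at 2694 against 815 CPM (1.73), RPL13 at 4350 against 1373 (1.66), RPL13A at 7528 against 2432 (1.63) and RPS16 at 2780 against 902 (1.62). After the trend was subtracted, 22 of the 44 were still higher. That count depends on the annotated GC content and deposited gene length, such as 9845 bases for RPS29, which may not be those of the expressed transcripts. Processed pseudogenes, many of which derive from such genes and can share their reads, were higher in 96 of 536 cases and lower in 49. Nuclear genes of oxidative phosphorylation were higher in 7 of 35 cases, led by CYC1 (1.28), NDUFV1 (1.26) and UQCRC1 (1.23), and lower in 1, NDUFV2 (-1.95). Their median was 0.72 (percentiles 98.3 and 99.6), but their mean of 0.52 lay at percentile 97.2 of level-matched lists, inside the central 95%. After the trend 8 of these genes were higher and 1 lower. The mitochondrially encoded subunits of the same complexes lay lower on balance: 3 of 13 passed the 2-fold rule, MT-ND6 (-1.27), MT-ND5 (-1.12) and MT-ND4L (-1.08), 0 were higher, and the median was -0.71 (percentiles 0.00 and 0.04). After the trend 0 of the 13 were higher and 2 lower. The mitochondrial ribosomal RNA MT-RNR2 took 3.31% of the reads in the AS1 library and 1.29% in the control library.

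Targets of NRF2, the transcription factor of the oxidative stress response, were higher as a group. Of 20 measured targets, 10 were at least 2-fold higher and 1 was lower, with a median log2 ratio of 0.99 (percentiles 99.9 and 100), and 9 were higher and 0 lower after the trend. AKR1C1 was at 37.6 against 6.35 CPM, the pentose phosphate enzyme TKT at 2236 against 516 (2.12), the ferritin light chain FTL at 4216 against 1103 (1.93) and OSGIN1 at 35.4 against 8.28 (2.09). The lower gene was the cystine transporter SLC7A11 (-1.28). The glutathione synthesis genes GCLC (-0.56) and GCLM (-0.41), the thioredoxin reductase TXNRD1 (-0.16) and the heme oxygenase HMOX1 (0.65), also targets of NRF2, did not pass. AKR1C1 and FTL have close paralogs or pseudogenes, so their values are uncertain where reads were shared. The list of unfolded protein and ATF4 target genes divided: 6 of 32 were higher, among them the amino acid synthesis genes ASNS (2.46) and PHGDH (2.02) and the pseudokinase TRIB3 (1.96), and 6 were lower, led by the endoplasmic reticulum chaperone HSP90B1 at 270 against 1212 CPM (-2.17). Its median was 0.34 (percentiles 41.2 and 46.2). Of 19 heat shock genes, 6 were lower, including HSP90AA1 at 235 against 1161 CPM (-2.31), HSPA4L (-2.02), CHORDC1 (-1.93) and HSPH1 (-1.44), and 2 were higher, HSPA1A (1.28) and HSPB1 (1.21). Their median was 0.35 (percentiles 40.5 and 49.8). After the trend, 0 heat shock genes were higher and 2 lower, while 7 unfolded protein and ATF4 target genes were higher and 2 lower. Within the heat shock list the log2 ratio rose with GC content (Spearman's rho 0.82).

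Genes of thyroid identity were low in both libraries. Of 21 thyroid differentiation genes 15 were listed and 12 had at least 10 reads, and DUOX2, an enzyme of hormone synthesis, passed the rule at 31 against 16 reads (1.23). The list's median was 0.11 (percentiles 76.0 and 56.7). Of 22 epithelial genes, 4 were higher, RAB25 (1.46), TJP3 (1.41), CLDN4 (1.08) and ELF3 (1.03), and 2 lower, the desmosomal gene DSP (-1.40) and the tight junction gene OCLN (-1.23), with a median of 0.63 (percentiles 88.7 and 32.4). In the mesenchymal list, ACTA2 (1.96) and SNAI1 (1.29) were higher and fibronectin, FN1, was lower (-1.40, 27.5 against 72.9 CPM) among 18 genes, with a median of 0.10 (percentiles 61.5 and 68.0). Among 18 matrix protease and adhesion genes, 5 were lower, the integrin subunits ITGA2 (-2.30), ITGAV (-1.74) and ITGA1 (-1.34) and the proteases MMP7 (-1.09) and MMP1 (-1.87), and 3 were higher, the integrin subunit ITGB4 (1.28), MMP11 (1.09) and ICAM1 (1.04). Their median was 0.60 (percentiles 88.3 and 90.2). Of 15 collagen and laminin genes, 4 were higher, COL6A1 (2.05), LAMB3 (1.29), LAMB2 (1.29) and COL18A1 (1.09), and 1 was lower, LAMA3 (-1.72), with a median of 0.64 (percentiles 92.1 and 79.5). After the trend, 0 thyroid genes passed in either direction, 0 epithelial genes were higher and 1 lower, and 2 mesenchymal genes were higher and 0 lower. For matrix proteases and adhesion 0 were then higher and 2 lower, and for collagens and laminins 1 was higher and 1 lower. Within the matrix protease and adhesion list the log2 ratio rose with GC content (Spearman's rho 0.83). Markers of other cell types were few. Of the fibroblast markers 1 was measured, FBLN2, at 9 against 2 reads. The endothelial list (4 measured; EGFL7 higher, 2.21), the leukocyte list (5 measured; CD14 higher, 1.27) and the melanocyte and neural list (3 measured; PMEL higher, 1.15) had level-matched percentiles of 75.7, 69.0 and 56.4 and GC-matched percentiles of 49.7, 39.8 and 50.9.

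**Figure D3:**
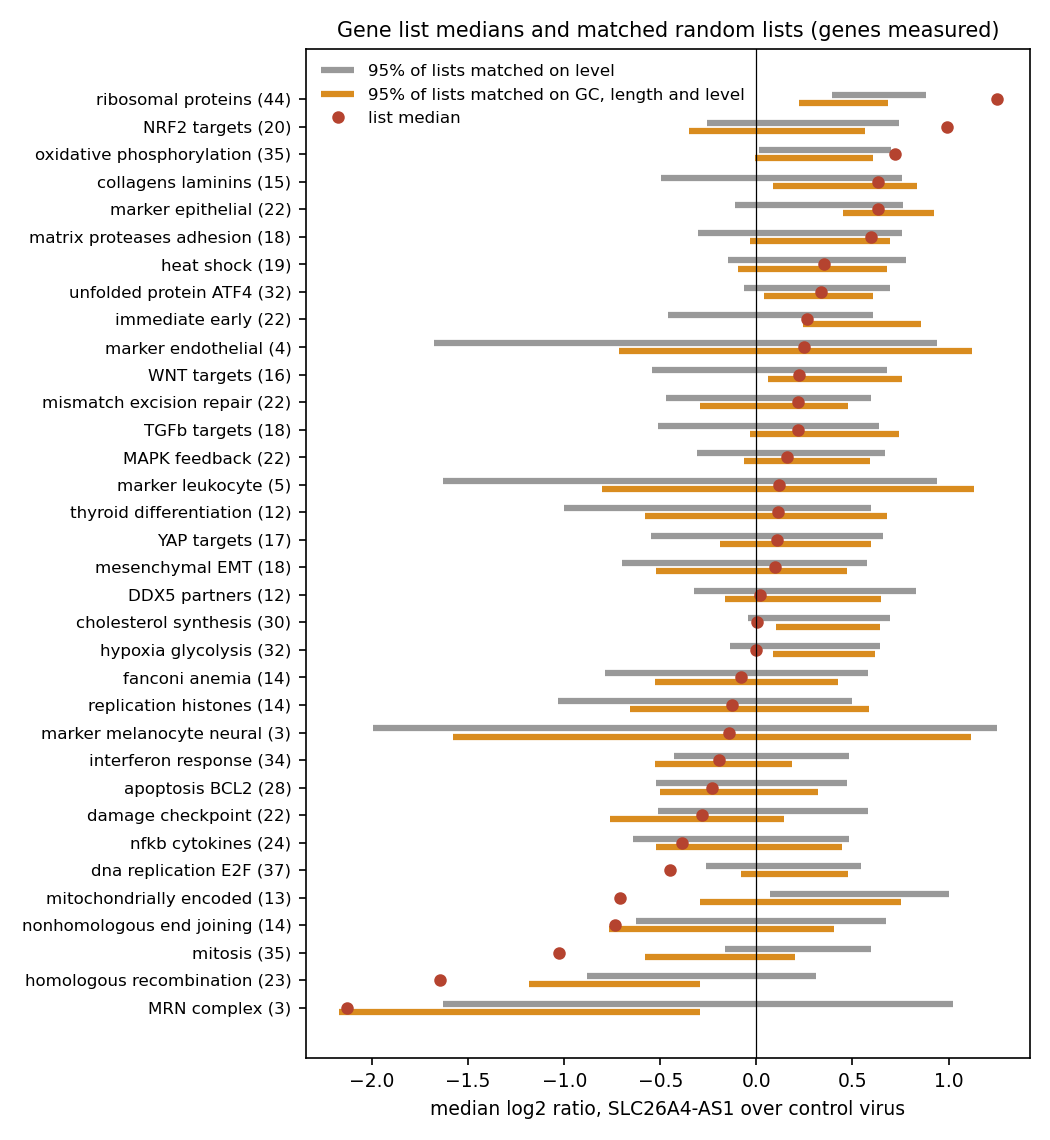
Median log2 ratio of each gene list reported (red points; AS1 over control library), with the number of measured genes in parentheses, beside the central 95% of random lists matched on level (grey) and on GC content, gene length and level (orange). Ribosomal protein genes, NRF2 targets and, narrowly, oxidative phosphorylation genes lie to the right of both ranges. Homologous recombination, mitosis, replication and mitochondrially encoded genes lie to the left of both.

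Signalling lists mostly held members of both directions. Of 34 interferon response genes, 7 were higher, including IFITM3 (1.63), and 11 lower, including SAMD9 (-2.97), the RNA sensor DDX58 (-1.94) and IFI44 (-1.95), with a median of -0.19 (percentiles 13.5 and 42.8), and 2 were higher and 5 lower after the trend. Of 24 NF-kB and cytokine genes, 8 were lower, led by BIRC3, the prostaglandin synthase PTGS2 (-2.73) and the chemokines CXCL8 (-2.37) and CXCL1 (-2.05), and 3 were higher, CCL5 (1.63), NFKB2 (1.34) and RELB (1.18), with a median of -0.39 (percentiles 11.9 and 6.85), and 5 were lower and 0 higher after the trend. Of 30 cholesterol synthesis genes, 5 were lower, among them HMGCS1 at 65.9 against 347 CPM (-2.40), SC5D (-2.08), IDI1 (-2.01) and STARD4 (-1.96), and 0 were higher. Their median of 0.01 lay at percentile 3.87 of level-matched and 0.80 of GC-matched lists. It ranked low because those lists centred above 0, at 0.387 and 0.391. Of 32 hypoxia and glycolysis genes, KDM3A (-1.44), BNIP3L (-1.20) and INSIG2 (-1.18) were lower and 0 higher, with percentiles of 7.87 and 0.77. Their median was -4.8e-04, and the matched lists centred on 0.31 and 0.37. Of 28 BCL2 family and apoptosis genes, 7 were lower, including BIRC2 (-2.15) and APAF1 (-1.67), and 4 higher, BCL2L1 (1.52), BBC3 (1.48), BMF (1.27) and CASP9 (1.01) (percentiles 16.4 and 24.7). The TGF-beta list had 3 of 18 genes higher, TGFB1 (1.22), BAMBI (1.16) and ID3 (1.24), and 3 lower, the receptor TGFBR1 (-1.84), SKIL (-1.61) and TGFB2 (-1.35) (percentiles 60.3 and 17.3). The YAP list had WWC1 (1.14) higher and MYOF (-1.21), F3 (-1.09) and TGFB2 (-1.35) lower among 17 genes (percentiles 43.9 and 26.6). The WNT list had NOTUM (2.41) and NKD2 (1.13) higher and LGR5 (-1.56) and DKK1 (-1.05) lower among 16 genes (percentiles 55.8 and 11.9). The MAPK feedback list had ETV4 (1.28) and DUSP5 (1.14) higher and SPRED1 (-1.14) and EREG (-1.12) lower among 22 genes (percentiles 34.8 and 21.9). Of 22 immediate early genes, EGR3 (-3.53) was lower, from few reads, and 0 were higher (percentiles 67.6 and 3.13). After the trend, 0 apoptosis genes were higher and 2 lower, and 0 TGF-beta genes were higher and 1 lower. No YAP gene then passed, and the WNT list had 1 higher and 1 lower. The cholesterol synthesis, hypoxia, MAPK feedback and immediate early lists each had 0 higher and 2 lower. Within the apoptosis and YAP lists the log2 ratio rose with GC content (Spearman's rho 0.86 and 0.80). In the interferon, NF-kB and cholesterol synthesis lists rho was 0.83, 0.84 and 0.80. The mean log2 ratio was below 0 while the median was above it for matrix proteases and adhesion (mean -0.18), heat shock (-0.16), cholesterol synthesis (-0.22), DDX5 partners (-0.12), mesenchymal (-0.07), immediate early (-0.04), YAP (-0.03) and mismatch and excision repair genes (-0.01), and the reverse held for melanocyte and neural markers (mean 0.29). Over the 36 lists, 35 had a percentile; 6 lay below and 3 above the central 95% of level-matched lists, and 6 below and 3 above that of GC-matched lists.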

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

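The GC and length trend, the GC-matched lists and the scaling as deposited were added after seeing the data, and the other alternatives were planned. Under the alternatives run, none of SLC26A4-AS1, DDX5, the 3 MRN genes and the 12 highest-ranked and 12 lowest-ranked genes changed direction. No scaling could have reversed them, since the largest shift was -0.35 and the log2 ratio nearest to no difference was -1.52 (MRE11). Other named genes were not recomputed one by one. With total counts 777 genes were at least 2-fold higher, against 1878 with TMM, because every log2 ratio shifts by -0.35, and with the upper quartile 2452 were higher and 2641 lower. The other scalings shift it by 0.11 (upper quartile), 0.018 (DESeq2 size factors) and -5.2e-05 (without mitochondrial genes). With the GC and length trend subtracted, 976 genes were higher and 1387 lower. A 1.5-fold limit gave 3964 higher and 4247 lower, a 4-fold limit gave 169 higher and 707 lower, an interval wholly beyond 2-fold gave 1042 and 1955, and a minimum of 10 CPM gave 1325 and 1967. Against the level of 3 control reads, SLC26A4-AS1 was 4381-fold higher with total counts and 6054-fold with the upper quartile. With total counts the log2 ratio was -1.87 for MRE11, -2.49 for NBN, -2.11 for DDX5 and 0.038 for TRIM25. With the upper quartile it was -1.64 for DDX5 and 0.50 for TRIM25. With the trend subtracted it was -0.29 for MRE11, -2.08 for RAD50, -0.83 for NBN and -1.03 for DDX5. Of the lists outside the central 95% of level-matched lists, MRN moved inside with lists matched on GC content (percentile 3.69, or 6.64 with mean GC content over transcripts), end joining with GC matching (3.09 and 4.91) and with the mean (4.07), and oxidative phosphorylation with the mean (97.2). Lists that moved outside were the damage checkpoint (0.06), cholesterol synthesis (0.63) and collagens and laminins (98.2) with the mean, hypoxia (0.77 and 0.41) and cholesterol synthesis (0.80 and 1.30) with both kinds of GC matching, and immediate early genes with mean GC content over transcripts (0.27). Apart from shifts that follow from the scaling constants, the cause was not tested. Homologous recombination, replication, mitosis, NRF2 targets, ribosomal proteins and mitochondrially encoded genes stayed outside on their side under every alternative run. Scaling by total counts, DESeq2 size factors or the upper quartile adds the same constant to every log2 ratio. It could not move any of these percentiles, so it is no check of them. Deposited FPKM, RPKM or TPM values were not run, since the files used here hold none. No paired analysis was possible because there is 1 library per group, which also rules out leaving out a replicate. Depth limits genes such as RAD50, with 12 reads in the AS1 library.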

Other observations

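Some abundant transcripts of both libraries are given here as values only. Both were rich in simple epithelial keratins, with KRT8 at 8566 CPM in the AS1 library and 6338 in the control library, KRT18 at 3448 and 1970, and the adhesion molecule EPCAM at 298 and 419. The mesenchymal filament gene VIM had 10 and 17 reads. A list of 20 intestinal epithelium genes, chosen after the data were seen, had 14 measured members. LGALS4 was at 1867 and 783 CPM, TSPAN8 at 317 and 452, HNF4A at 95.5 and 79.5, and KRT20 at 58.1 and 92.8. The antibacterial enzyme LYZ was at 1287 and 1290 CPM. High keratin and EPCAM levels with so few VIM reads are unusual for a line from an anaplastic thyroid carcinoma. The identity of the cells rests on the labels and was not tested, so each result holds for the cells sequenced, whichever line they are.

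Members of the same family or pathway differed. The cytosolic chaperone HSP90AA1 was lower (-2.31) while its paralog HSP90AB1 was at 3339 against 2119 CPM (log2 ratio 0.66). CYP1A1, ALDH3A1 and NQO1 (1.27), targets of the aryl hydrocarbon receptor, were higher, but other genes of a list of 8 such targets chosen after the data were seen, 7 of them measured, did not pass the 2-fold rule: TIPARP (0.03), CYP1B1 (-0.15), UGT1A6 (-0.06) and AHRR (-0.46). The list's median was 0.03 (percentiles 35.2 and 45.4 of level-matched and GC-matched lists), and that of the intestinal list was 0.16 (percentiles 54.4 and 38.4). Among genes far from the GC and length trend, chosen after their values were seen, CLSPN (-3.16, and -2.75 after the trend) lay below it and EIF3F (1.61, and 2.64 after the trend), a translation initiation factor gene, above it. For EIF3F the trend was taken at 40.6% GC and a deposited length of 9431 bases. If the expressed transcript differs from these, the distance from the trend is misstated.

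Of the tests below, those of overlapping genes, of 3' UTR composition and of the NRF2 paralog families were set out before their result was seen, and the others after it. The 3 MRN genes have AT-rich transcripts, and their lower level may in part follow the trend with GC content and length. Their median lay at percentile 3.69 of lists matched on these properties and level, inside the central 95%, against 0.30 of lists matched on level alone. With 3 genes, that median is the value of NBN. After the trend is subtracted, MRE11 and NBN no longer pass the 2-fold rule (-1.52 to -0.29, and -2.13 to -0.83). Missing that limit does not show that the trend accounts for them, and NBN stayed lower. Among the 200 genes nearest in GC content, length and level, MRE11 lay at percentile 47, close to their median of -1.45. NBN lay at percentile 13 of its own 200 nearest genes, whose median was -1.39. Whether the trend covers RAD50 stays open: from 12 reads, it was at -2.08 after the trend and at percentile 2.5 of the 200 genes nearest in GC content, length and level, at the edge of the central 95%. Overlapping and other genes differed in median by -0.00962 on the log2 scale after the trend. A loss of reads to overlapping genes that was alike in both libraries would cancel in the ratio. The value therefore cannot decide whether overlap lowered MRE11, NBN or RAD50, and none of them was tested alone.

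The trend with GC content is the widest pattern in these libraries. Within each of 5 groups by deposited gene length the rank correlation with GC content was at least 0.560, so the trend was not one of that length alone. Deposited gene length need not be the length of the transcripts present, so these groups cannot decide whether long transcripts were lost. The partial rank correlation with coding GC content at fixed 3' UTR GC content was 0.395 over 10596 genes. At fixed coding GC content, that with 3' UTR GC content was 0.362, so both parts were related to the ratio to a similar degree. Both GC values came from an annotated transcript, which may not be the expressed one. An inexact 3' UTR value can leave a correlation with coding GC content. These values therefore cannot decide whether 3' UTR composition alone is enough. A GC-dependent bias of library preparation or sequencing remains a candidate explanation: it should also touch noncoding genes, and among 416 lincRNA and antisense genes the correlation was 0.458. That is weaker than the 0.767 of protein-coding genes, and among 155 processed pseudogenes it was 0.279. A response of the cells to SLC26A4-AS1 that favours GC-rich transcripts cannot be told apart from it, because each group has 1 library.

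NRF2 targets lay off that trend. At a median GC content of 46.8%, their median of 0.99 lay above all lists matched on GC content, length and level (percentile 100), so the trend is not enough to account for it. Reads shared within families are also argued against as the whole source, since 14 members without the AKR1B, AKR1C and ferritin genes had a median of 0.68, at percentile 98.15. That is close to the edge of the central 95%, and 5 of the 14 were at least 2-fold higher. Higher NRF2 activity in the cells with the SLC26A4-AS1 virus is a hypothesis these data leave open; SLC7A11 went the other way (-1.28), GCLC, GCLM and TXNRD1 did not follow it, and a difference between the cultures unrelated to the virus was not tested, with 1 library per group.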
